A study of Mus musculus with 8 samples.

How the data were processed

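RNA was extracted from sorted EpCAM+CD45- lung cells of mice with a spin-column kit and DNase treatment, and stranded mRNA libraries were prepared, per the labels. The data are a table of counts per gene as deposited by the authors: whole-number read counts for 43432 mouse Ensembl genes in 8 libraries, not normalised. The submitters' processing notes name the aligner STAR 2.4.2a and DESeq2 without giving their roles, and they name the build GRCh38, a human build, whereas the gene identifiers are those of mouse. The counting tool, strand setting, read filters and annotation release are not given in the sources used here. Reads that align to several genes may therefore have been dropped or assigned, which bears on near-identical genes such as Hspa1a and Hspa1b, Lyz1 and Lyz2, C4b and its paralog, the haemoglobin beta genes, and Rpl26 and its processed copy. Columns were assigned to samples from their names, in which w stands for the wild-type allele, with the replicate numbers of the titles. Symbols and positions were taken from GENCODE M21 on GRCm38, which gave a symbol for 42462 identifiers and none for 970; no coordinate came from the authors.

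Genes were filtered with filterByExpr by group, which left 14906 tested genes, and libraries were scaled by TMM factors (0.915 to 1.06). One edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with a mean per group was fitted to all 8 libraries. Each pair of groups was compared with a two-sided F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM are TMM-scaled, and log2 fold changes are those of the edgeR fit. The sharing of 1 spread by all groups was chosen because groups of 3 and 2 give few degrees of freedom, and no block was used because the labels do not say that replicate numbers pair libraries. Total counts of 17057216 to 52319957 per library limit what can be seen: counting error is small for genes above a few CPM, and the spread between libraries sets the precision. A fold against a group at 0 uses a floor of 3 counts per library, which covers counting error only.

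The 25 gene lists (epithelial, immune, endothelial and stromal markers, and pathways fitting chitinase, type 2 immunity, stress, metabolism and proliferation), the tests and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for C/+ against WT and for C/C against C/+; C/C against WT has counts of calls only. None of the list calls holds with a correlation estimated per list, and the adjusted p so obtained stands beside each call. The count adjusted over the list alone applies the adjustment within the list. Fry, a rotation test of whether a list's genes move on balance in 1 direction, was an alternative. Some genes, such as Cyp2f2, Pdpn and Clca1, are in 2 or more lists. Named genes are Chia1 and the chitinase family; per comparison the 12 largest increases and 12 largest decreases among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, without predicted or unnamed genes; and from each list up to 4 called members with the highest mean CPM, or up to 2 where none was called. All calls would be named in a direction with 10 or fewer.

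The model was tested on simulated data with each gene's mean level and fitted dispersion, in which 100 genes changed 2-fold and 100 changed 4-fold. It found 59% and 88% of these between C/+ and WT, 56% and 81% between C/C and C/+, and 62% and 83% between C/C and WT, with 11, 5 and 2 false calls. Camera found the moved list in each. For a list that was not moved its p was 0.265, 0.719 and 0.0383, the last under 0.05 although no change was simulated. Genes were simulated independently, so these results do not show how camera behaves where the genes of a list move together. No 2 libraries of a group held the same values or agreed within sampling noise (chi-square per gene 12.2 to 73.5). Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of 1 CPM in 5 libraries, the compared groups alone, a replicate block, a test against a 1.5-fold change, and leaving out each library. Sex as a covariate, thinning to the smallest library, female libraries alone and the mean level of the immediate early list as a covariate were added after the data were seen. Sex was read from Xist and Y-linked counts, since the labels give none. Overlaps between comparisons were set against 50 simulated sets. Nothing in the table was left out except the filtered genes.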

Results

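Gene expression was measured by RNA sequencing in 8 libraries of EpCAM+CD45- cells, an epithelial gate that leaves out CD45+ leukocytes, from the lungs of 14-week-old C57BL/6J mice. Wild-type mice (WT, n = 3) gave the whole EpCAM+CD45- gate. Mice with 1 copy (C/+, n = 3) or both copies (C/C, n = 2) of ChiaRed gave the ChiaRed+ part of that gate. ChiaRed is a reporter of Chia1, which encodes acidic mammalian chitinase (AMCase). WT and reporter libraries therefore differed in sorting as well as in genotype. Total counts were 36362406, 20232091 and 52319957 in WT, 30190458, 21239201 and 17057216 in C/+, and 46478577 and 41950581 in C/C. All 8 libraries were dominated by alveolar type 2 transcripts: Sftpc, the surfactant protein C gene, stood at 121031 ± 14509 CPM in WT, 142305 ± 5763 CPM in C/+ and 165119 ± 2271 CPM in C/C. Values are mean ± SD over the libraries of a group in CPM (counts scaled to the same library total), with 3 libraries for WT and for C/+ and 2 for C/C, and changes are given as log2 fold changes (log2FC) with their standard errors (SE). Mitochondrially encoded genes took 3.04% ± 0.234 of counts in WT, 4.87% ± 1.34 in C/+ and 5.80% ± 1.24 in C/C. The sexes were mixed across groups: WT 1, C/+ 2, C/+ 3 and both C/C libraries had Xist at 271 to 699 CPM and nearly no Y-linked reads. WT 2, WT 3 and C/+ 1 had Ddx3y at 51.9 to 54.9 CPM. Sex and group were thus partly aligned, and only C/C and C/+ had at least 2 libraries each of 1 sex (female). The labels do not say that libraries came from separate animals, although the sexes show more than 1 animal within WT and within C/+. The p-values measure the spread between these samples, part of which may be technical, and in C/C all of it.

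The first question was how much of the reporter's own gene each group expressed. Chia1 (ENSMUSG00000062778, chromosome 3, 106113229 to 106132120 on the plus strand of GRCm38) stood at 382 ± 100.5 CPM in WT and 289 ± 60.1 CPM in C/+, a difference that was not called (log2FC -0.40, SE 0.28, adjusted p = 0.476). It fell to 0.905 ± 0.764 CPM in C/C, against C/+ (log2FC -8.28, SE 0.50, adjusted p = 0.000124) and against WT (log2FC -8.68, SE 0.51, adjusted p = 3.96e-05). The C/C libraries held 63 and 14 Chia1 counts, and the other 6 libraries held 3795 to 22881. Chil1, a chitinase-like gene without known chitinase activity, was the most abundant family member, at 5772 ± 602 CPM in WT, 5616 ± 577 CPM in C/+ and 6404 ± 696 CPM in C/C. Neither Chil1 nor the lysosomal and other family members Chid1, Ctbs, Ovgp1, Chil3 and Chil6 was called in any of the 3 comparisons. Of the 7 tested family genes, 0 were called between C/+ and WT by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2), and 1, Chia1, was called in each of the other comparisons. The family as a list was not called by camera between C/+ and WT (camera adjusted p = 0.277) or between C/C and C/+ (camera adjusted p = 0.228). Fry called it between C/C and C/+ (fry adjusted p = 0.0125), but the list includes Chia1, so this is not separate evidence about the rest of the family. Within 2 Mb of Chia1, 43 other genes were tested, of which 2 were called between C/C and C/+ and 0 between C/C and WT. Over all 14906 tested genes, 1056 and 444 were called in these comparisons.

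**Figure D1:**
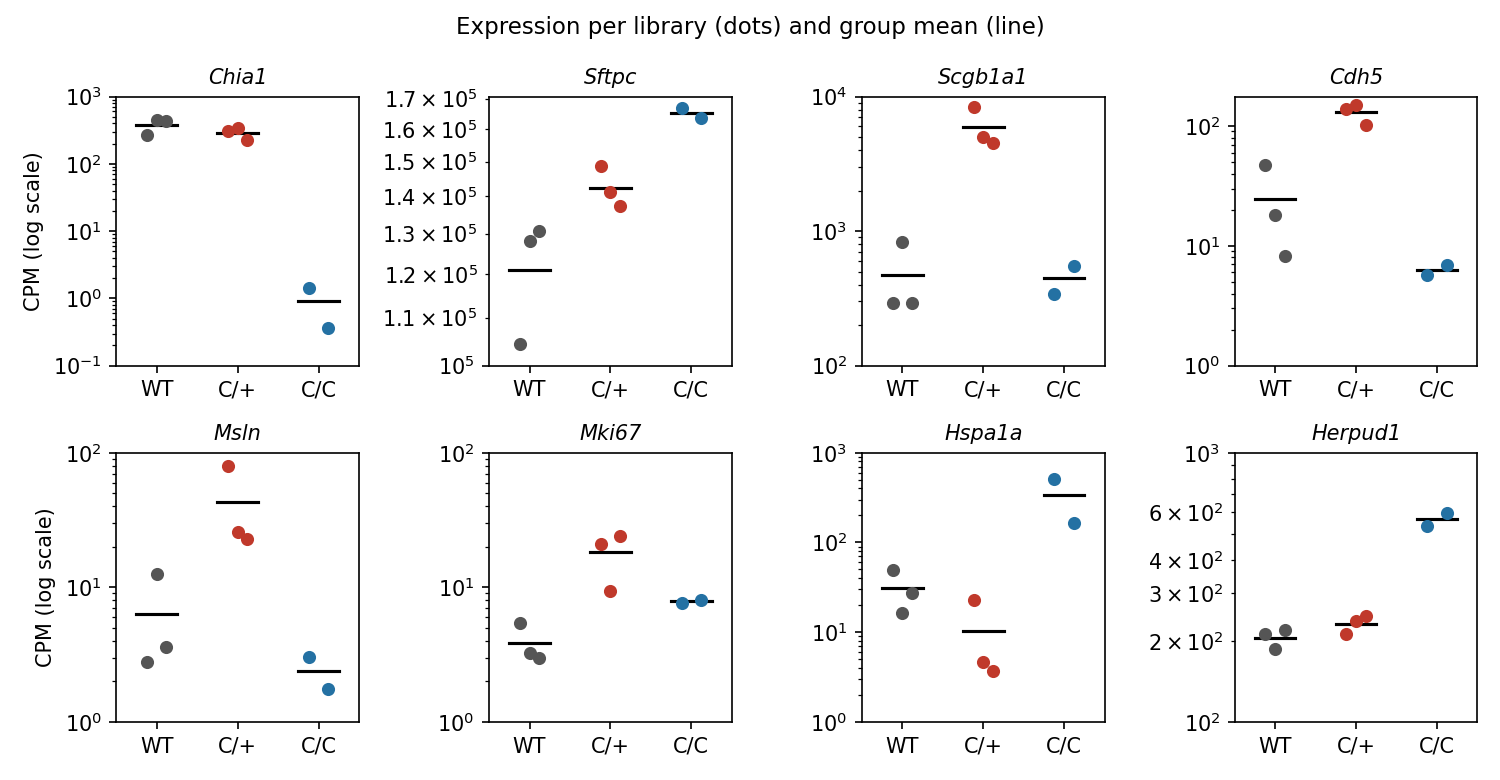
Expression of 8 genes in each library, in CPM on a log axis, for WT, C/+ and C/C; dots are libraries and lines are group means. Chia1 is at 1.45 and 0.365 CPM in C/C 1 and C/C 2, Scgb1a1, Cdh5, Msln and Mki67 have their highest mean in C/+, and Hspa1a and Herpud1 have theirs in C/C.

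The comparison of C/+ with WT asked which transcripts differ between heterozygous ChiaRed+ cells and the whole epithelial gate. Of 14906 tested genes, 585 were called, 510 higher and 75 lower in C/+. Scgb1a1, which encodes the main secretoglobin of club cells, rose from 468 ± 308 CPM in WT to 5966 ± 2115 CPM in C/+ (log2FC 3.67, SE 0.44, adjusted p = 0.00906). Called higher were also 12 of 12 endothelial markers, 6 of 7 mesothelial markers and 11 of 16 cell cycle genes. Camera called these 3 lists, each at adjusted p = 0.427 with an estimated correlation. Of the alveolar type 2 markers, 1 of 18 was called.

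Of the club markers, 10 of 17 tested were called higher (14 adjusted over the list alone), with a list median log2 fold change of 1.79. The airway secretory (club) markers had camera adjusted p = 1.35e-09, and adjusted p = 0.427 with an estimated correlation. Scgb3a2, another secretoglobin, rose from 13.5 ± 7.31 CPM in WT to 129.8 ± 68.4 CPM in C/+ (log2FC 3.30, SE 0.42, adjusted p = 0.00906). Cyp2f2, a cytochrome P450 of club cells, rose from 137 ± 45.7 CPM in WT to 501 ± 128 CPM in C/+ (log2FC 1.87, SE 0.24, adjusted p = 0.00906), and Aldh1a1, an aldehyde dehydrogenase gene, rose as well (log2FC 1.79, adjusted p = 0.0161). Bpifa1 and Bpifb1, secreted airway proteins, had log2 fold changes of 4.51 and 2.94, with SDs in C/+ of 72.9 and 22.2 CPM around means of 80.6 and 35.2. Xenobiotic metabolism genes, which share Cyp2f2, Cyp2a5 and Gsta3 with the club list, had 9 of 22 called higher (10 adjusted over the list alone). The xenobiotic metabolism genes had camera adjusted p = 0.000107, and adjusted p = 0.427 with an estimated correlation. Called members included Fmo2, Cyp4b1, Gsta3 and Cyp1a1, with log2FC of 1.37, 1.30, 0.53 and 3.15 (largest adjusted p = 0.0452). Of the goblet and mucin genes, 1 of 8 was called. Muc5b, a secreted mucin, rose from 2.03 ± 0.957 CPM in WT to 12.05 ± 8.99 CPM in C/+ (log2FC 2.61, adjusted p = 0.0314). The goblet and mucin list was not called (camera adjusted p = 0.122).

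All 12 endothelial markers were called higher in C/+ (also 12 adjusted over the list alone), with a median log2 fold change of 2.31. The endothelial markers had camera adjusted p = 3.89e-10, and adjusted p = 0.427 with an estimated correlation. Cdh5, the endothelial cadherin, rose from 24.5 ± 20.2 CPM in WT to 130.3 ± 25.3 CPM in C/+ (log2FC 2.41, SE 0.48, adjusted p = 0.0254). Pecam1, Vwf and Calcrl rose with it, with log2FC of 2.4, 2.49 and 2.19 (largest adjusted p = 0.0315). Of the mesothelial markers, 6 of 7 were called higher (7 adjusted over the list alone; median 2.74). The mesothelial markers had camera adjusted p = 1.26e-06, and adjusted p = 0.427 with an estimated correlation. Msln, the mesothelin gene, rose from 6.32 ± 5.43 CPM in WT to 42.8 ± 32.1 CPM in C/+ (log2FC 2.83, adjusted p = 0.034), and Upk3b rose with it (log2FC 2.71, adjusted p = 0.0161). Of the mesenchymal markers, 5 of 11 were called higher (6 adjusted over the list alone). The mesenchymal markers had camera adjusted p = 7.1e-05, and adjusted p = 0.502 with an estimated correlation. They included the proteoglycan genes Bgn and Dcn and the collagen gene Col3a1, with log2FC of 2.39, 2.30 and 2.48 (largest adjusted p = 0.0334). Scn7a, Kit and Aplnr, which are in none of the fixed lists, also rose, with log2 fold changes of 2.54, 2.45 and 2.38. Cav1, fixed as an alveolar type 1 marker and also abundant in endothelium, rose from 29.1 ± 6.91 CPM in WT to 110.0 ± 38.6 CPM in C/+ (log2FC 1.92, adjusted p = 0.00977). The WT libraries were uneven in these lists: WT 1 had the highest mean endothelial level of the 3 and WT 2 the highest mesothelial level.

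Of the cell cycle genes, 11 of 16 were called higher (14 adjusted over the list alone), with a median log2 fold change of 2.25. The cell cycle genes had camera adjusted p = 3.89e-10, and adjusted p = 0.427 with an estimated correlation. Mki67, a marker of cycling cells, rose from 3.87 ± 1.34 CPM in WT to 18.2 ± 7.79 CPM in C/+ (log2FC 2.23, SE 0.34, adjusted p = 0.0116). Top2a, a DNA topoisomerase, rose from 3.60 ± 1.27 CPM in WT to 17.01 ± 6.51 CPM in C/+ (log2FC 2.25, adjusted p = 0.0139). Interferon response genes were called as a list, although 1 of 18 members was called (also 1 adjusted over the list alone), Oasl2 (log2FC 0.93, adjusted p = 0.0221). The interferon response genes had camera adjusted p = 0.00183, and adjusted p = 0.53 with an estimated correlation.

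Of the lipid synthesis genes of surfactant production, 3 of 16 were called lower (8 adjusted over the list alone; median -0.31). The surfactant lipid synthesis genes had camera adjusted p = 0.000774, and adjusted p = 0.485 with an estimated correlation. Srebf1, a lipogenic transcription factor, fell from 379.9 ± 4.66 CPM in WT to 283 ± 27.8 CPM in C/+ (log2FC -0.42, adjusted p = 0.0427). Pcyt1a, an enzyme of phosphatidylcholine synthesis, fell from 164 ± 19.7 CPM in WT to 112 ± 0.850 CPM in C/+ (log2FC -0.55, adjusted p = 0.0199). Of the MHC class II genes, 1 of 8 was called lower (also 1 adjusted over the list alone). The MHC class II genes had camera adjusted p = 0.00706, and adjusted p = 0.53 with an estimated correlation. Ciita, the class II transactivator, fell from 45.7 ± 5.42 CPM in WT to 31.9 ± 2.28 CPM in C/+ (log2FC -0.52, adjusted p = 0.0331). The ciliated markers were called lower as a list, with 0 of 18 members called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2). The ciliated cell markers had camera adjusted p = 0.0427, and adjusted p = 0.686 with an estimated correlation. Their mean log2 CPM was 2.83 in C/+ 1, above the 2.36, 2.47 and 2.76 of WT, and 1.85 and 1.75 in C/+ 2 and C/+ 3. The surfactant lipid, MHC class II and ciliated lists were the 3 called lower. That number was 1 with sex as a covariate, chosen after the data were seen, 1 without WT 2, 1 without WT 3 and 1 without C/+ 3. It was 5 without WT 1, 6 without C/+ 1 and 2 without C/+ 2. Among called genes at 10 CPM or more in WT, the largest decline was that of Slc26a4, an anion exchanger, from 52.8 ± 21.8 CPM in WT to 22.8 ± 7.79 CPM in C/+ (log2FC -1.22, adjusted p = 0.0464). Kcnf1, Ndnf, Tle3 and the clock repressor Cry1 followed, with log2FC of -0.98, -0.97, -0.82 and -0.73 (largest adjusted p = 0.0462). Also lower were Avpr1a, P2ry2, Tmem28, Nebl, Ndst1, Usp9x and Arrdc3, with log2 fold changes from -0.73 to -0.64.

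Few alveolar markers were called. Of the alveolar type 2 markers, 1 of 18 was called. Lyz1 rose from 2416 ± 557 CPM in WT to 4366 ± 698 CPM in C/+ (log2FC 0.85, adjusted p = 0.0302); its reads are hard to separate from those of its neighbour Lyz2. The type 2 list's median was -0.05 and its mean 0.02, with a camera direction of down (adjusted p = 0.791). Of the alveolar type 1 markers, Cav1 was called higher and Rtkn2 lower (log2FC -1.34, adjusted p = 0.0181), and the list was not called (camera adjusted p = 0.0639). No call was made by edgeR among the basal, neuroendocrine, tuft, leukocyte and alveolar macrophage markers. At an unadjusted p under 0.05 the counts were 1, 0, 3, 0 and 3 in that order, and DESeq2 called 0, 0, 1, 0 and 1. The same held for the type 2 immune response, inflammatory cytokine, unfolded protein response, fibrosis and senescence, immediate early and haemoglobin genes. Here the counts at an unadjusted p under 0.05 were 5, 2, 1, 7, 1 and 3 in that order, and DESeq2 called 0, 0, 0, 3, 0 and 0. Camera called none of these 11 lists, the lowest adjusted p being 0.131. The haemoglobin median was 2.65, or 2.58 with the gene listed at 0 in WT set at its bound, and it rested on C/+ 1: the list's mean log2 CPM was 0.31, -3.51 and -3.74 in C/+ and -2.72, -4.05 and -3.91 in WT. In all, 10 of 25 lists were called, and 0 with an estimated correlation (0 at an unadjusted p under 0.05, 5 by fry).

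Of the 585 called genes, 584 had no overlap between the libraries of the 2 groups, which held for 24.8% of all tested genes against the 10% that chance gives. The count fell to 127 without WT 2, 175 without WT 3, 103 without C/+ 1, 198 without C/+ 2, 331 without C/C 1 and 330 without C/C 2. The share called higher, 87.2%, was 61.6% with sex as a covariate (1047 higher and 653 lower), 73.6% by DESeq2 (907 higher and 326 lower) and 72.7% without a low-count filter (944 higher and 355 lower). In every fit that left out 1 library, 11 of 64 called named genes kept the call, among them Bgn, Cav1, Ccnb2, Cyp2f2, Gabrp, Pkhd1l1, Scgb1a1, Scgb3a2, Scn7a and Vwf.

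**Figure D2:**
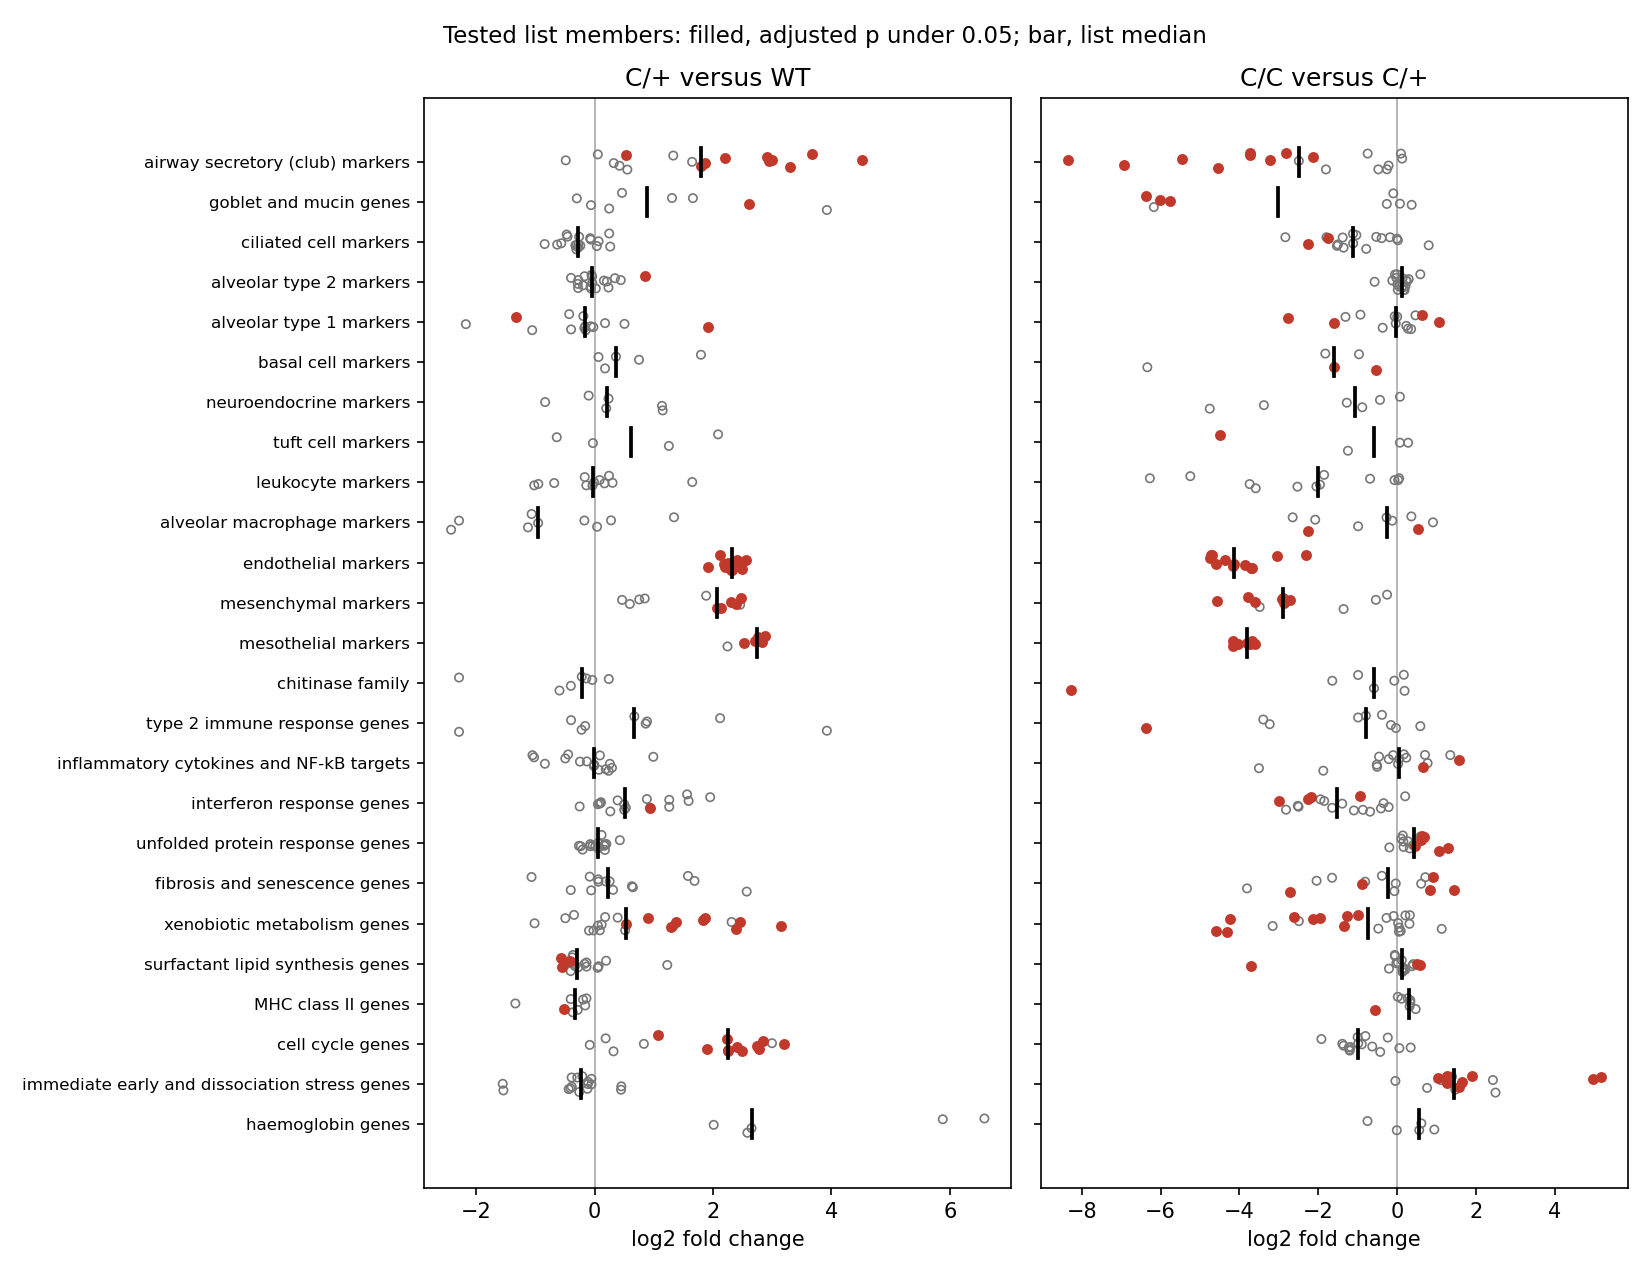
Log2 fold changes of the tested members of the 25 gene lists, for C/+ versus WT (left) and C/C versus C/+ (right); each dot is a gene, filled where adjusted p was under 0.05, and each bar is the list's median. The endothelial median is 2.31 on the left and -4.14 on the right, and the immediate early median is -0.23 on the left and 1.43 on the right.

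The comparison of C/C with C/+ took the ChiaRed+ part of the gate in both groups. It asked which transcripts differ between cells with Chia1 transcript and those with nearly none. The groups also differ in copies of ChiaRed, so a change in which cells pass the gate cannot be told apart from loss of Chia1. In all, 1056 genes were called, of which 261 were higher and 795 lower in C/C. Plk3, a polo-like kinase gene, rose from 6.78 ± 0.894 CPM in C/+ to 39.1 ± 1.89 CPM in C/C (log2FC 2.52, SE 0.22, adjusted p = 0.0006). Called lower were 9 of 17 club, 12 of 12 endothelial, 7 of 7 mesothelial and 7 of 11 mesenchymal markers and 4 of 18 interferon response genes. Camera called these 5 lists, each at adjusted p = 0.263 with an estimated correlation. Scgb1a1 fell from 5966 ± 2115 CPM in C/+ to 446 ± 146 CPM in C/C (log2FC -3.74, SE 0.52, adjusted p = 0.0027). None of the 18 alveolar type 2 markers was called by edgeR (3 at an unadjusted p under 0.05, 2 by DESeq2), and their median was 0.13 (camera adjusted p = 0.0892).

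Of the immediate early and dissociation stress genes, 9 of 16 were called higher in C/C (15 adjusted over the list alone), with a median log2 fold change of 1.43. The immediate early and dissociation stress genes had camera adjusted p = 1.16e-08, and adjusted p = 0.263 with an estimated correlation. Zfp36, which encodes an mRNA-destabilising protein, rose from 772 ± 201 CPM in C/+ to 1845 ± 19.9 CPM in C/C (log2FC 1.26, SE 0.26, adjusted p = 0.0168). Btg2, Nr4a1, Jund and Egr1, all transcriptional regulators, rose as well, with log2FC of 1.65, 1.56, 1.26 and 1.90 (largest adjusted p = 0.0391). Fos and Jun were not called, at 2715 ± 572 CPM and 1722 ± 310.5 CPM in C/C against 1034 ± 369.8 CPM and 794 ± 169 CPM in C/+. Hspa1a rose from 10.4 ± 10.7 CPM in C/+ to 338 ± 244 CPM in C/C (log2FC 4.97, SE 0.76, adjusted p = 0.00384). Hspa1b rose from 8.17 ± 7.35 CPM in C/+ to 307 ± 239.5 CPM in C/C (log2FC 5.17, adjusted p = 0.00549). The 2 genes are near-identical, so the split of reads between them is uncertain, and their SDs in C/C were large. Other chaperone genes that rose were Hsph1, Hspb1 and Dnaja1, with log2FC of 2.34, 2.05 and 1.92 (largest adjusted p = 0.0338). Rgcc rose from 50.4 ± 4.08 CPM in C/+ to 231 ± 16.2 CPM in C/C (log2FC 2.19, adjusted p = 0.000335). The transcription factor gene Klf6 and the kinase gene Sik1 had log2FC of 2.21 and 1.82 (largest adjusted p = 0.0118). Gem, a small GTPase gene, rose from 35.3 ± 5.31 CPM in C/+ to 118 ± 9.04 CPM in C/C (log2FC 1.74, adjusted p = 0.0006). Hs3st3b1, a heparan sulfate sulfotransferase gene, rose from 6.04 ± 1.40 CPM in C/+ to 20.9 ± 2.90 CPM in C/C (log2FC 1.79, adjusted p = 0.0114).

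Genes of the unfolded protein response in the endoplasmic reticulum formed the other list that rose. Of its members, 6 of 16 were called (9 adjusted over the list alone), with a median of 0.43. The unfolded protein response genes had camera adjusted p = 4.48e-07, and adjusted p = 0.263 with an estimated correlation. Herpud1, a component of endoplasmic reticulum-associated degradation, rose from 232 ± 18.2 CPM in C/+ to 567 ± 45.3 CPM in C/C (log2FC 1.29, SE 0.12, adjusted p = 0.0006). Hspa5, the chaperone BiP, rose from 437 ± 41.9 CPM in C/+ to 671 ± 85.03 CPM in C/C (log2FC 0.62, adjusted p = 0.0163). Xbp1, Manf, Dnajb9 and Creld2 rose too, with log2FC of 0.45, 0.61, 1.07 and 0.69 (largest adjusted p = 0.0347). Hsp90b1 was not called, at 617 ± 0.955 CPM in C/C and 551 ± 36.4 CPM in C/+. From other lists, the NF-kB targets Nfkbiz and Nfkbia, the cell cycle inhibitor Cdkn1a, the keratin gene Krt8 and Gdf15 also rose, with log2FC of 1.57, 0.65, 0.84, 0.92 and 1.45 (largest adjusted p = 0.0454).

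All 12 endothelial markers fell (also 12 adjusted over the list alone), with a median of -4.14. The endothelial markers had camera adjusted p = 1.45e-12, and adjusted p = 0.263 with an estimated correlation. Cdh5 fell from 130.3 ± 25.3 CPM in C/+ to 6.34 ± 0.915 CPM in C/C (log2FC -4.36, SE 0.63, adjusted p = 0.00311), and Vwf, Pecam1 and Calcrl had log2FC of -3.04, -4.13 and -4.73 (largest adjusted p = 0.00311). All 7 mesothelial markers fell (also 7 adjusted over the list alone; median -3.82), with Msln at 2.399 ± 0.923 CPM in C/C (log2FC -4.15, adjusted p = 0.00997). The mesothelial markers had camera adjusted p = 1.21e-07, and adjusted p = 0.263 with an estimated correlation. Of the mesenchymal markers, 7 of 11 fell (8 adjusted over the list alone). The mesenchymal markers had camera adjusted p = 3.35e-06, and adjusted p = 0.263 with an estimated correlation. Among these were Bgn, Col3a1 and the elastin gene Eln, with log2FC of -2.92, -3.61 and -4.58 (largest adjusted p = 0.00835). Of the club markers, 9 of 17 fell (12 adjusted over the list alone; median -2.49). The airway secretory (club) markers had camera adjusted p = 3.67e-08, and adjusted p = 0.263 with an estimated correlation. Scgb3a2 fell from 129.8 ± 68.4 CPM in C/+ to 5.61 ± 0.565 CPM in C/C (log2FC -4.53, adjusted p = 0.00141). Cyp2f2 fell from 501 ± 128 CPM in C/+ to 115 ± 11.7 CPM in C/C (log2FC -2.12, adjusted p = 0.0022), and Scgb3a1 to 0.403 ± 0.274 CPM (log2FC -6.93, adjusted p = 0.00244). Of the xenobiotic metabolism genes, 9 of 22 fell (13 adjusted over the list alone). The xenobiotic metabolism genes had camera adjusted p = 0.000597, and adjusted p = 0.263 with an estimated correlation. They included Fmo2, Cyp4b1 and Cyp2s1, with log2FC of -1.28, -1.97 and -1.34 (largest adjusted p = 0.0335). Of the interferon response genes, 4 of 18 fell (11 adjusted over the list alone). The interferon response genes had camera adjusted p = 6.93e-07, and adjusted p = 0.263 with an estimated correlation. Oasl2, an interferon-induced gene, fell from 19.8 ± 3.40 CPM in C/+ to 4.13 ± 0.318 CPM in C/C (log2FC -2.26, adjusted p = 0.000689). Irf7, Gbp2 and Ifi44 fell with it, with log2FC of -0.93, -2.18 and -3.0 (largest adjusted p = 0.0262).

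Ciliated markers fell as a list, with 2 of 18 members called (11 adjusted over the list alone; median -1.12). The ciliated cell markers had camera adjusted p = 0.00321, and adjusted p = 0.532 with an estimated correlation. The called members were the axonemal genes Dnah9 and Spag17, with log2FC of -1.76 and -2.25 (largest adjusted p = 0.0329). Of the 11 fixed basal markers 5 were tested, and Trp63, Krt14, Krt17 and Ngfr were among those filtered out. The 5 tested basal markers fell as a list, with 2 called (also 2 adjusted over the list alone). Their mean log2 CPM was 2.02 in C/+ 1, 0.61 and 0.74 in C/+ 2 and C/+ 3, and -0.15 and 0.22 in C/C. The basal cell markers had camera adjusted p = 0.0193, and adjusted p = 0.263 with an estimated correlation. The called genes were Itga6 (log2FC -0.54, adjusted p = 0.0314) and Pdpn (log2FC -1.61, adjusted p = 0.0331), the latter also an alveolar type 1 marker. Cell cycle genes were called lower as a list with 0 of 16 members called by edgeR (9 at an unadjusted p under 0.05, 4 by DESeq2). The cell cycle genes had camera adjusted p = 0.00595, and adjusted p = 0.541 with an estimated correlation. Of the goblet and mucin genes, 3 of 8 fell, with Muc5b from 12.05 ± 8.99 CPM in C/+ to 0.222 ± 0.0545 CPM in C/C (log2FC -5.76, adjusted p = 0.0027). Clca1, also fixed as a type 2 immune response gene and the only call of that list, and Tff2 were near the detection floor in C/C. The list medians were -3.01 for goblet and mucin genes (-1.03 with genes at 0 set at their bound), -1.08 for neuroendocrine markers (-0.78) and -2.00 for leukocyte markers (-1.88). The leukocyte difference rested on C/+ 1: the mean log2 CPM was 1.36, -0.47 and -0.85 in C/+ and -0.92 and -0.70 in C/C. No call was made by edgeR among neuroendocrine markers, leukocyte markers and haemoglobin genes. At an unadjusted p under 0.05 the counts were 1, 1 and 0 in that order, and DESeq2 called 1, 1 and 0. Single genes were called from lists that were not: Plcb2 of the tuft markers, Plet1 (up) and Fabp4 (down) of the alveolar macrophage markers, and Ciita of the MHC class II genes. Ciita fell from 31.9 ± 2.28 CPM in C/+ to 21.5 ± 0.496 CPM in C/C (log2FC -0.56, adjusted p = 0.0243). Of the surfactant lipid genes Hmgcs1 rose and Elovl6, at under 1 CPM, fell. Of the alveolar type 1 markers Gprc5a and Rtkn2 rose and Cav1 and Pdpn fell, and Pdgfb of the fibrosis and senescence list fell, as did Tgfb2, a member chosen for naming after its value was seen. The alveolar type 1, alveolar macrophage and fibrosis lists had medians and means under 0 with a camera direction of up, and the inflammatory and surfactant lipid lists had means under 0 with medians and directions above it. Among lists not called by camera the lowest adjusted p was 0.0847. In all, 11 of 25 lists were called, and 0 with an estimated correlation (1 at an unadjusted p under 0.05, 12 by fry). Of the 12 lists called by fry, 9 were among the 11. Fry did not call the ciliated and cell cycle lists (fry adjusted p = 0.203 and 0.213). It called the goblet and mucin, type 2 immune response and chitinase lists (fry adjusted p = 0.0341, 0.0203 and 0.0125), the last of which includes Chia1 itself.

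The club marker Bpifa1 fell from 80.6 ± 72.9 CPM in C/+ to 0.233 ± 0.255 CPM in C/C (log2FC -8.36, adjusted p = 0.00502). Outside the lists, the antimicrobial lectin gene Reg3g fell to 0.0735 ± 0.00661 CPM (log2FC -7.21, adjusted p = 0.00561). Its C/C level is near the floor of 3 counts per library, so the size of its fall is uncertain. Ltf was lower as well (log2FC -9.42, adjusted p = 0.00816), with C/C at 0.0130 ± 0.0184 CPM, under the floor of 3 counts per library. Rpl26, a ribosomal protein gene, fell from 52.1 ± 32.2 CPM in C/+ to 0.898 ± 0.167 CPM in C/C (log2FC -5.86, SE 0.62, adjusted p = 0.000986); reads of Rpl26 can also align to a near-identical processed copy, Gm15772. Piezo2, Aplnr, Scn7a and Kit had log2FC of -5.44, -5.34, -5.32 and -5.20 (largest adjusted p = 0.0022). All 1056 called genes had no overlap between the libraries of the groups, against 38.3% of tested genes and the 20% that chance gives. The count fell to 185 without C/C 1 and 244 without C/C 2, fits in which the lone C/C library is assumed to vary like the other groups. Across the fits that left out 1 library, 33 of 102 called named genes kept the call in all, among them Chia1, Plk3, Rgcc, Herpud1, Scgb3a2, Cyp2f2, Calcrl and Oasl2. With female libraries alone, chosen after the data were seen, 892 genes were called, 237 higher and 655 lower, of which 787 were among the 1056.

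**Figure D3:**
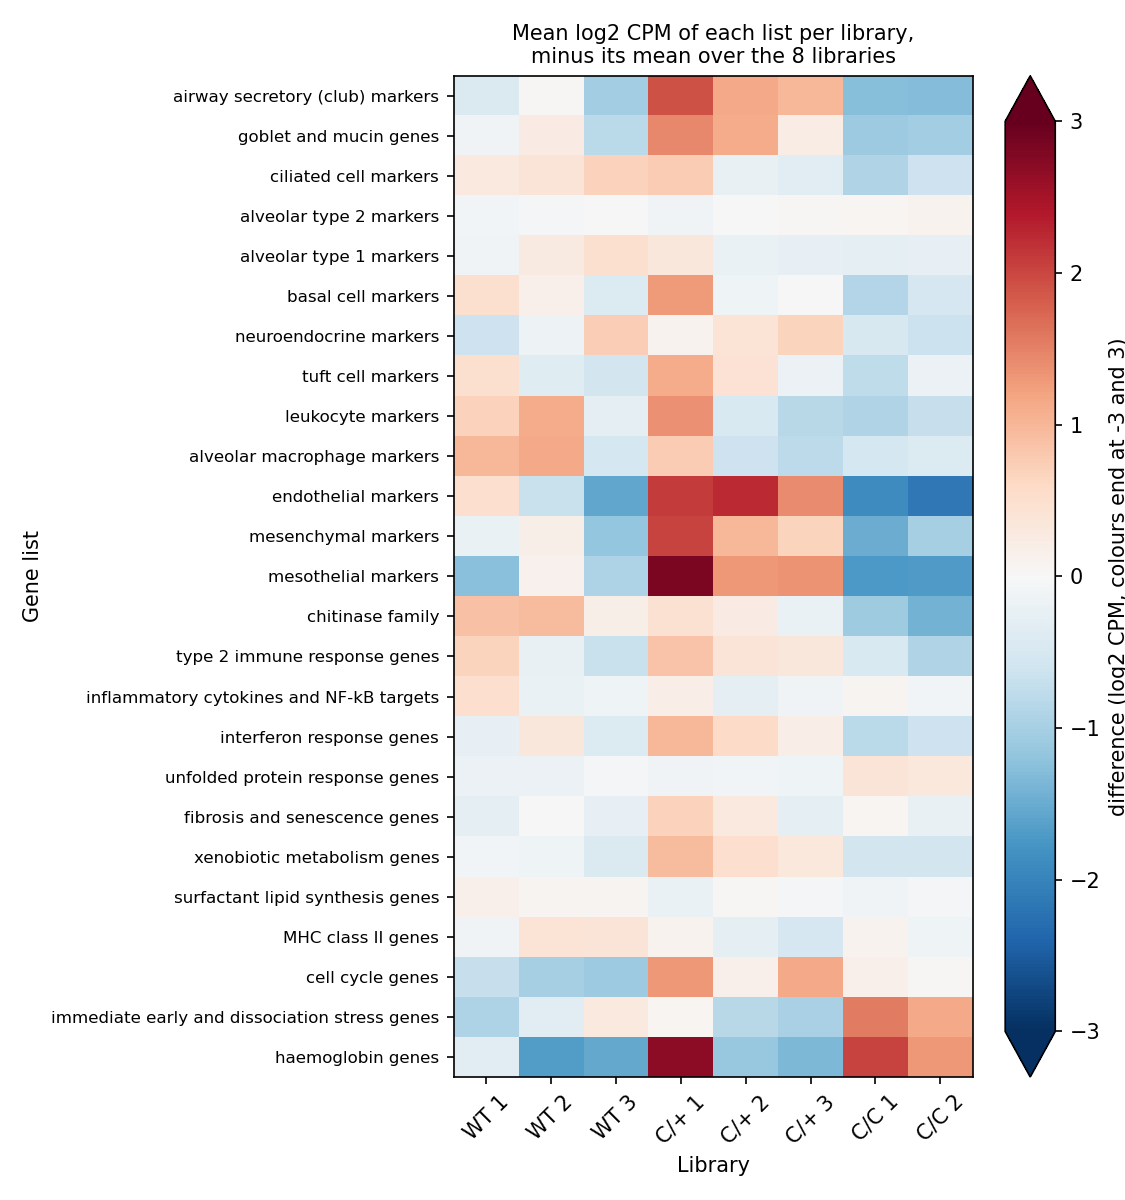
Mean log2 CPM of each gene list in each library minus its mean over the 8 libraries, from blue (lower) to red (higher), with colours ending at -3 and 3. Columns are libraries and rows are lists; endothelial, mesothelial and mesenchymal lists are red in the 3 C/+ libraries, and the immediate early list is red in the 2 C/C libraries.

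The comparison of C/C with WT set ChiaRed+ cells with nearly no Chia1 transcript against the whole gate. In this comparison 444 genes were called, of which 241 were higher and 203 lower in C/C. Rgcc rose from 30.3 ± 6.63 CPM in WT to 231 ± 16.2 CPM in C/C (log2FC 2.93, SE 0.16, adjusted p = 3.96e-05), and Plk3 and Gem had log2FC of 2.84 and 2.33 (largest adjusted p = 0.000229). The clock gene Per1 rose from 42.6 ± 9.29 CPM in WT to 217 ± 5.10 CPM in C/C (log2FC 2.35, adjusted p = 0.000276). Glul, the glutamine synthetase gene, rose from 106 ± 11.9 CPM in WT to 455 ± 46.1 CPM in C/C (log2FC 2.10, adjusted p = 3.96e-05). Sik1, Csrnp1, Maff and F3, the tissue factor gene, rose too, with log2FC of 1.89, 1.99, 1.60 and 1.83 (largest adjusted p = 0.0391), as did Hspa1a and Hspa1b, with log2FC of 3.43 and 3.62 (largest adjusted p = 0.0413). Unfolded protein response genes had 6 of 16 called higher (11 adjusted over the list alone). Herpud1 rose from 206 ± 16.8 CPM in WT to 567 ± 45.3 CPM in C/C (log2FC 1.46, adjusted p = 0.000261), and Manf rose as well (log2FC 0.80, adjusted p = 0.00829). Immediate early genes had 4 of 16 called higher (13 adjusted over the list alone), namely Zfp36, Jund, Hspa1a and Hspa1b.

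Of the ciliated markers, 5 of 18 were called lower than in WT (11 adjusted over the list alone). Foxj1, the transcription factor of motile ciliogenesis, fell from 17.98 ± 1.44 CPM in WT to 4.75 ± 0.548 CPM in C/C (log2FC -1.92, SE 0.41, adjusted p = 0.0392). Dnah9, Hydin, Cdhr3 and Spag17 fell with it, with log2FC of -2.4, -1.96, -1.98 and -2.56 (largest adjusted p = 0.0488). Outside the list, the axonemal genes Dnah6, Dnah3 and Cfap65 fell, with log2FC of -2.32, -2.20 and -1.67 (largest adjusted p = 0.0425). Tppp3 and Dynlrb2, the most abundant ciliated markers, were not called, at 133 ± 15.7 CPM and 26.4 ± 0.935 CPM in C/C and 125 ± 33.8 CPM and 24.98 ± 1.73 CPM in WT. Wnt3a, which encodes a secreted WNT ligand, fell from 10.7 ± 1.63 CPM in WT to 0.221 ± 0.0198 CPM in C/C (log2FC -5.58, SE 0.67, adjusted p = 0.00392). Rpl26 fell from 56.5 ± 17.6 CPM in WT to 0.898 ± 0.167 CPM in C/C (log2FC -5.98, adjusted p = 0.00173). Its reads can also align to the copy Gm15772, and the summed CPM of both differed by -0.64 on the log2 scale. Ciita, Oasl2, the interleukin 4 receptor gene Il4ra and Cyp2s1 were lower, with log2FC of -1.08, -1.33, -0.60 and -1.68 (largest adjusted p = 0.0334). Of the endothelial markers, 1 of 12, Calcrl, was called lower (9 adjusted over the list alone), and the median was -1.73. Scgb1a1 was at 446 ± 146 CPM in C/C against 468 ± 308 CPM in WT and was not called (log2FC -0.07, adjusted p = 0.951). Of the club markers, Hp was called higher and Scgb3a1 lower.

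Other lists held 2 calls or fewer between C/C and WT. The interferon, MHC class II, type 2 immune response, xenobiotic metabolism and chitinase lists had 1 call each, the genes Oasl2, Ciita, Il4ra, Cyp2s1 and Chia1. Cell cycle genes had 2 of 16 called higher, Pcna and Ccnb2 (9 adjusted over the list alone). The inflammatory list had 2 of 16, Nfkbiz and Nfkbia, and the fibrosis and senescence list 2 of 14, Krt8 and Cdkn1a; the fibrosis list's median was 0.39 and its mean -0.11. The alveolar type 1 list had Gprc5a higher and Clic5 lower, and the alveolar macrophage list had Plet1 higher. No member was called by edgeR among the alveolar type 2, goblet and mucin, basal, neuroendocrine, tuft, leukocyte, mesenchymal, mesothelial, surfactant lipid and haemoglobin lists. At an unadjusted p under 0.05 the counts were 6, 3, 2, 1, 1, 3, 2, 0, 4 and 2 in that order, and DESeq2 called 4, 2, 2, 0, 0, 2, 1, 0, 2 and 0. Lists were not tested as sets in this comparison. All 444 called genes had no overlap between libraries of the groups, against 43.3% of tested genes and the 20% that chance gives. The count fell to 39 without WT 2, 281 without WT 3, 178 without C/+ 2, 30 without C/C 1 and 33 without C/C 2 and rose to 782 without C/+ 3. Which direction held more calls turned with the setting: 638 higher and 770 lower by DESeq2, 639 and 709 with sex as a covariate, 607 and 849 without a low-count filter and 73 and 103 with the replicate number as a block. It also turned without WT 3 (124 higher and 157 lower) and without C/+ 1 (227 higher and 260 lower). Of the 55 called named genes, 12 kept the call in every fit that left out 1 library: Cdkn1a, Chia1, F3, Gem, Glul, Herpud1, mt-Rnr1, Per1, Plk3, Rgcc, Rpl26 and Sik1.

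The comparisons overlapped. Of the 510 genes higher in C/+ than in WT, 359 were lower in C/C than in C/+, where 27.2 would be shared by chance between independent gene sets. Scgb1a1, Cdh5 and Msln were among them. Of the 261 genes higher in C/C than in C/+, 111 were also higher in C/C than in WT (4.22 by chance), among them Rgcc, Plk3 and Herpud1. Lower in C/C than in both other groups were 103 genes (10.8 by chance), including Chia1, Wnt3a and Oasl2. Rpl26 was among them too, although reads shared with its copy Gm15772 may account for its fall. The genes higher than WT in both C/+ and C/C numbered 40 (8.25 by chance), Rgcc and Glul among them, and those lower than WT in both numbered 16 (1.02 by chance), such as Ndst1 and Ciita. Of the genes lower in C/+ than in WT, 7 were higher in C/C than in C/+ (1.31 by chance), including Arrdc3 and Tle3. Each pair of comparisons shares the libraries of 1 group, which can make overlaps on its own, and groups of 3 and 2 libraries are too small to split. In 50 simulated sets without group differences at most 1 gene was shared for any pair. That value leaves out the effects, under which many more genes are called, so part of the observed excess may come from the shared libraries.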

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

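The sex covariate, the thinned libraries, the female libraries alone and the immediate early covariate were chosen after the data were seen. With fits that left out 1 library, the called genes numbered 103 to 729 for C/+ against WT, 185 to 1308 for C/C against C/+ and 30 to 782 for C/C against WT, and the called lists 8 to 13 and 10 to 12; fewer samples were fitted, and a lone C/C library was assumed to vary like the others. Without a low-count filter the counts were 1299, 1614 and 1456 in the same order, with 22726 genes tested. Against a 1.5-fold change they were 131, 564 and 21, a stricter question by construction. With sex as a covariate they were 1700, 1200 and 1348, and with the DESeq2 Wald test 1233, 1555 and 1408; 585, 989 and 416 of the genes called in the report kept their call with sex. With the 2 compared groups alone they were 356, 1125 and 588. With the immediate early covariate 412 genes were called between C/C and C/+, 219 of them among the 1056. The cause was not tested for the filter, sex, DESeq2, group and covariate settings. With the replicate number as a block the gene counts were 457, 799 and 176, and the lists 11 and 14. Residuals of libraries with the same number correlated between -0.21 and 0.09. Libraries with different numbers were not compared, so these values do not show whether the numbers pair libraries. DESeq2 size factors gave 601, 1058 and 450 genes, the 1 CPM filter 449, 733 and 529, and thinning 570, 895 and 370. Of 25 lists, camera called 0 and 0 with an estimated correlation, against 10 and 11 with the preset one. At an unadjusted p under 0.05 the estimated correlation gave 0 and 1. Fry called 5 and 12. An estimated correlation widens the test where it is above the preset one. That setting also uses the few residual degrees of freedom of the fit, which raises p by itself. The loss of the camera calls may therefore come in part from the method, and the 2 effects were not separated. The loss still limits every list call. Named genes reversed direction in 0 called values; of 221 called values, 2 were no longer called with the Wald test, 1 with sex, 27 with the compared groups alone and 58 with the block, and 15 to 133 when 1 library was left out. Genes near the floor of 3 counts per library, such as Ltf, Reg3g, Clca1, Tff2 and Elovl6 in C/C, are limited by depth.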

Other observations

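The tests of endothelial cells, depth, sex, cell mixture, the immediate early covariate, the glucocorticoid response, the near-identical copy and the linked interval, with their lists and the mitochondrial genes, were chosen only after the patterns were seen. Of 18 tested genes of a list of glucocorticoid-induced genes written afterwards, 7 were called higher in C/C than in C/+ by edgeR, and the list was not tested as a set. Besides Per1 and Glul, these were Tsc22d3, which encodes the anti-inflammatory protein GILZ (log2 fold change 0.88, SE 0.16), Errfi1, a feedback inhibitor of EGFR (1.25, SE 0.14), Cebpd (1.46, SE 0.25), Klf9 (0.67, SE 0.16) and the sodium channel gene Scnn1a (0.63, SE 0.16). Fkbp5, a common glucocorticoid marker, was not called (0.19, SE 0.30), and Sgk1, Pdk4, Angptl4 and Cdkn1c, not called either, had log2 fold changes of -0.07, -0.29, -0.68 and -0.45.

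Of 16 tested mitochondrially encoded genes, 6 were called higher in C/C than in WT: mt-Rnr1, mt-Rnr2, mt-Nd1, mt-Co1, mt-Nd4 and mt-Cytb. Over the 16 the log2 fold changes ran from -0.49 to 1.78 with a median of 0.82, and no set test was run. Between C/+ and WT 2 were called higher, mt-Nd1 and mt-Cytb (median 0.67), and between C/C and C/+ 1, mt-Rnr1 (median 0.35).

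Of 30 tested endothelial, mesothelial and mesenchymal markers, 23 were called higher in C/+ than in both WT and C/C. Library depth and sex are argued against as the whole cause. Of the 23 members, picked for having both calls, 23 kept both after every library was thinned to the smallest total. With sex as a covariate 23 kept both. Keeping a call was common among all called genes. Thinning kept 511 of 585 for C/+ against WT and 857 of 1056 for C/C against C/+, and the sex covariate kept 585 and 989. Endothelial cells in the C/+ sort stay a candidate explanation, although the EpCAM+ gate would remove them. Of a further endothelial list, 15 of 20 genes were called in both comparisons, short of an 80% limit set after the data were seen. In that list 19 of 20 had log2 fold changes above 1 and below -1, and Esam was flat in both. The abundant markers Cdh5 and Vwf reached 130.3 and 99.9 CPM in C/+. Expression of Chia1 or of the reporter in such cells, a biological difference named by the design, was not tested.

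Of the listed immediate early, heat shock and unfolded protein response genes, 15 were called higher in C/C than in C/+. Fewer cells of other types in C/C would raise alveolar type 2 markers alike, but their median log2 fold change was 0.13 (upper quartile 0.21), under the lower quartile of 1.22 over all tested immediate early genes, which argues against it for these; for all tested unfolded protein response genes the lower quartile was 0.16 (median 0.43), which leaves it open, and these quartiles replaced those of the called genes alone. Handling before lysis stays open: with the immediate early score as a covariate the median of the 6 unfolded protein response genes was 0.51, against 0.66 without it, while the median SE rose from 0.11 to 0.22, and 1 was still called. A glucocorticoid response may contribute and cannot be told apart. Of 18 induced genes 7 were called higher, against 261 of all 14906 tested genes. That share is under the 50% set for it and above the 20% set against it, limits written after the data were seen. The 7 include Per1 and Glul, already named among the largest increases of C/C over WT. An effect of the C/C genotype, including loss of Chia1, stays open and untested.

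Rpl26, Wnt3a and the unnamed transcript 2610507I01Rik, on chromosome 11 between positions 59199836 and 68906989, were low in C/C, at 0.898, 0.221 and 0.286 CPM, as was the club gene Scgb3a1 at 0.403, on the same chromosome at 49663610. For Rpl26, reads shared with Gm15772, a processed copy on chromosome 5 with 436 of 438 bases identical, may account for the fall: Gm15772 rose from 0.143 CPM in WT to 35.4 in C/C, and the sum of both differed by -0.64 on the log2 scale, against -5.97 for Rpl26 alone. In C/+, Gm15772 stood at 18.4, 0.233 and 14.1 CPM and Wnt3a at 3.07, 6.76 and 1.24 in libraries 1, 2 and 3. The split between Rpl26 and Gm15772 did not follow the group in C/+, where library 2 was within the WT range of 0.0744 to 0.259 CPM for Gm15772. Shared reads alone do not say why it differed between libraries. A linked interval that carries other variants in C/C stays open, although Chia1 itself lies on chromosome 3. The share of called genes cannot decide it, because that share changes with the ends chosen. Between 2610507I01Rik and Rpl26, 7 of 109 other tested genes (6.42%) were called between C/C and WT, against 2.93% elsewhere (two-sided Fisher's exact p = 0.043). With Scgb3a1 as the start it was 9 of 219 (4.11%, two-sided Fisher's exact p = 0.309). No variant or reporter insertion was examined. The ends were set from the genes of the pattern, leaving out Scgb3a1 and taking in Wnt3a, and no p is adjusted for the others; an earlier exact hypergeometric test for chromosome 11 (one-sided p = 0.0025) ran on Rpl26, Scgb3a1, 2610507I01Rik and Rn7sk, the genes that raised the question, and so supports nothing.

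The 6 libraries of WT and C/+ can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 585 genes and was 1 of 10 with as many; the highest other count was 6, in the split that follows sex. For the gene lists, 2 of 10 splits gave as many as the real one, 10, and the highest other count was 10.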
